A study of Mus musculus with 27 samples.

How the data were processed

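PolyA RNA of Ba/F3 cells, a mouse pro-B line, was sequenced by the authors from libraries made with the TruSeq RNA kit. The 27 libraries were assigned to 7 groups from their labels, which call the libraries of a group biological replicates. The deposited files held raw whole-number counts of reads per gene symbol, 1 file per library, with 5 summary lines for reads not assigned to a gene. Per the submitters' processing notes, these counts came from a pipeline that named Trimmomatic 0.30, TopHat2 2.0.10, HTSeq 0.5.4p5, DESeq2 1.2 and the mm10 build. The order of these steps, the counting mode and the gene annotation were not given in the sources used here. Gene positions were taken from GENCODE vM21 (GRCm38/mm10) by symbol. The summary lines were left out of library sizes and tests, and served only to describe the libraries. No library was left out.

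Depth ranged from 5.48 to 33.8 M counted reads per library. Levels are counts per M reads counted in genes (CPM), scaled by trimmed mean of M values (TMM) factors, and are given as mean ± SD over the libraries of a group. A gene without reads was given the limit that 3 counts would set, which covers counting error only, because copies made by PCR were not told apart from independent molecules.

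All 27 libraries entered 1 edgeR quasi-likelihood fit with a mean per group and no covariate (R 4.3.3, edgeR 4.0.16, limma 3.58.1). The robust option, TMM factors and the filterByExpr filter were used, which left 12073 genes. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested) with no minimum fold change. The 8 comparisons were IL3-stimulated against deprived wild-type cells, each knockdown against the no-target hairpin, the no-target hairpin against stimulated wild type, STAT5A against STAT5B knockdown, and LSD1 against HDAC3 knockdown. The last pair tests whether 2 knockdown effects differ, since both have the same controls.

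A total of 25 gene lists was fixed before the data were examined, as were the tests, the groups, the alternatives to try and the rule for naming genes. Each list with measured members was tested with limma's camera on log2 CPM (prior count 2, preset correlation between genes 0.01, two-sided), adjusted over the lists of a comparison. The test was repeated with a correlation estimated from the data and with limma's fry, which asks whether the genes of a list move, on balance, one way and compares the list with no other genes. Members called are given over all genes tested and adjusted over the list alone. Genes called in the wild-type comparison with an absolute log2 fold change of at least 1 formed an IL3-induced and an IL3-repressed set. These were tested in the knockdowns, which share no library with the wild-type comparison. The mean log2 CPM of each set was also compared as a score per library by an exact two-sided permutation test over all 56 splits of 3 against 5 libraries.

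The text names Stat5a, Stat5b, Kdm1a and Hdac3; a core set of 15 cytokine-response genes; and, per comparison, up to 8 of the largest rises and 8 of the largest falls. The latter were taken among called genes with a mean CPM of at least 5 and no overlap between groups, leaving out predicted models, small RNAs and pseudogenes. It also names up to 4 called members of each list with the smallest adjusted p, and up to 6 genes changed in the same direction in most knockdowns. Any other gene is named as chosen after its values were seen. A few genes that this rule names are not reported here, although they remain in the counts.

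Similarity of 2 knockdown effects was measured by the Pearson correlation and covariance of their log2 fold changes across genes. Because the knockdowns share 5 controls, the values were set beside 50 simulations of unchanged groups against shared controls. They were also recomputed with the controls divided between the 2 knockdowns in 20 ways.

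The pipeline was tested on simulated data with 200 changed genes per comparison. It recovered 44 to 75% of genes changed 2-fold and 86 to 98% of genes changed 4-fold, and 2.88 to 7.47% of calls were false. A shifted list was found in 8 of 8 comparisons and an unshifted list in 0 of 8. Counts were drawn independently per gene, without library classes, pairing or correlation between genes. The simulated rates of false calls therefore need not hold for the real libraries.

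Whether equal replicate numbers pair the libraries was checked by correlating deviations from group means across genes. In wild type, all 5 same-numbered pairs correlated (r 0.375 to 0.716), so a fit with the replicate number as a block was added there. In the remaining comparisons, at most 2 of 3 pairs did. No 2 replicates were copies of each other: over 42 pairs, the chi-square per degree of freedom was 10.0 to 160.

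Alternatives tried were relative log expression (RLE) factors, no filter on low counts (20571 genes), DESeq2 1.42.0, a fit of only the 2 groups compared, a replicate block, a threshold of 0.01, a minimum fold, and leaving out each library in turn. Alternatives chosen after seeing the data were a term for library class, leaving out 5 libraries with many reads outside genes, and the wild-type block. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.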

Results

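PolyA RNA was sequenced from Ba/F3 cells, a mouse pro-B line that depends on the cytokine IL3. Wild-type cells were deprived of IL3 for 6 h (n = 5 libraries), or deprived for 6 h and then given IL3 at 10 ng/mL for 30 min (n = 5). Cells carrying a lentiviral short hairpin were deprived and stimulated in the same way. The hairpins had no target (n = 5) or targeted STAT5A, STAT5B, LSD1 or HDAC3 (n = 3 each). STAT5A and STAT5B are transcription factors activated by the IL3 receptor. LSD1, a histone demethylase encoded by Kdm1a, and HDAC3, a histone deacetylase, are parts of co-repressor complexes. Reads counted in genes ranged from 14.4 to 31.2 M per library in deprived and 12.7 to 33.8 M in stimulated wild type. They ranged from 6.93 to 17.6 M with the no-target hairpin, 11.7 to 22.6 M in the STAT5A, 8.53 to 18.8 M in the STAT5B, 5.54 to 21.4 M in the LSD1 and 5.48 to 12.2 M in the HDAC3 knockdown.

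The libraries also differed in ways their groups do not explain. In 5 libraries, 14.0 to 24.9% of reads fell outside genes, against 8.70 to 12% in the remaining 22. These were HDAC3 knockdown replicates 1 and 2, LSD1 knockdown replicate 1 and no-target replicates 1 and 3, and they held 5.48 to 7.53 M counted reads. They lay between 44.2 and 80.3 on the main principal component, which carried 35.4% of the variance, while the others lay between -59.8 and 8.94. A further 4 libraries (replicate 3 of the STAT5A and replicate 2 of the STAT5B knockdown, and replicate 2 of each wild-type group) had 0.177 to 0.190 multi-mapped reads per counted read, against 0.200 to 0.295 elsewhere. The 18 libraries outside both classes are called the common class here. The classes were read from the data and are not groups of the study.

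**Figure D1:**
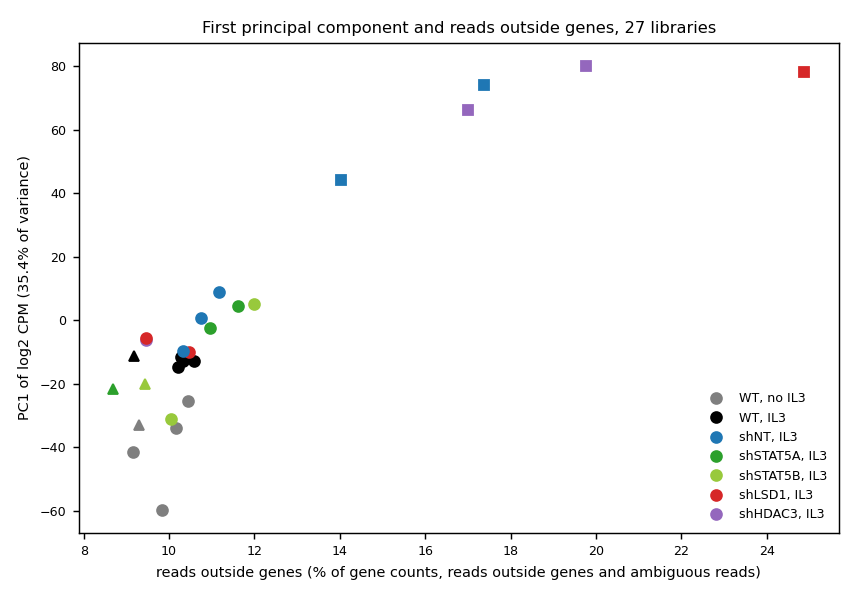
Score on the main principal component (y axis, no unit) against the percent of reads outside genes (x axis) for each of the 27 libraries, coloured by group. Squares mark the 5 libraries with 14.0 to 24.9% of reads outside genes, triangles the 4 with few multi-mapped reads and circles the other 18, and the squares stand apart at 44.2 or higher.

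Each hairpin lowered its own target. Stat5a (GRCm38/mm10, GENCODE vM21, chromosome 11, 100859351 to 100885169, plus strand) stood at 26 ± 2.03 CPM (SD, n = 3) in the STAT5A knockdown against 72.3 ± 14.8 (SD, n = 5) with the no-target hairpin (log2 fold change -1.48, SE 0.18, adjusted p = 0.000254). Stat5b (chromosome 11, 100780731 to 100850724, minus strand) stood at 33.0 ± 3.40 CPM in the STAT5B knockdown against 116 ± 16.2 (log2 fold change -1.81, SE 0.17, adjusted p = 9.84e-07). Kdm1a (chromosome 4, 136550540 to 136602723, minus strand) stood at 77 ± 23.9 CPM in the LSD1 knockdown against 145 ± 10.6 (log2 fold change -0.91, SE 0.14, adjusted p = 0.00126). Hdac3 (chromosome 18, 37935844 to 37955016, minus strand) stood at 58.2 ± 22.2 CPM in the HDAC3 knockdown against 132 ± 23.1 (log2 fold change -1.18, SE 0.18, adjusted p = 0.0130). Remaining transcript was 32.7 to 38.0% of control for Stat5a and 25.3 to 31.1% for Stat5b. It ranged from 38.1 to 70.6% for Kdm1a and from 34.1 to 63.7% for Hdac3, so the LSD1 and HDAC3 libraries differed in how much target was left. None of the 4 genes passed the test in the knockdown of another. Fitted with only the 2 groups compared, Stat5a, Kdm1a and Hdac3 no longer passed, with log2 fold changes of -1.48, -0.91 and -1.16. Hdac3 also no longer passed without HDAC3 knockdown replicate 2 (-1.02) or 3 (-1.01) or no-target replicate 2 (-1.10), and Kdm1a without the 5 libraries with many reads outside genes (-0.90).

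**Figure D2:**
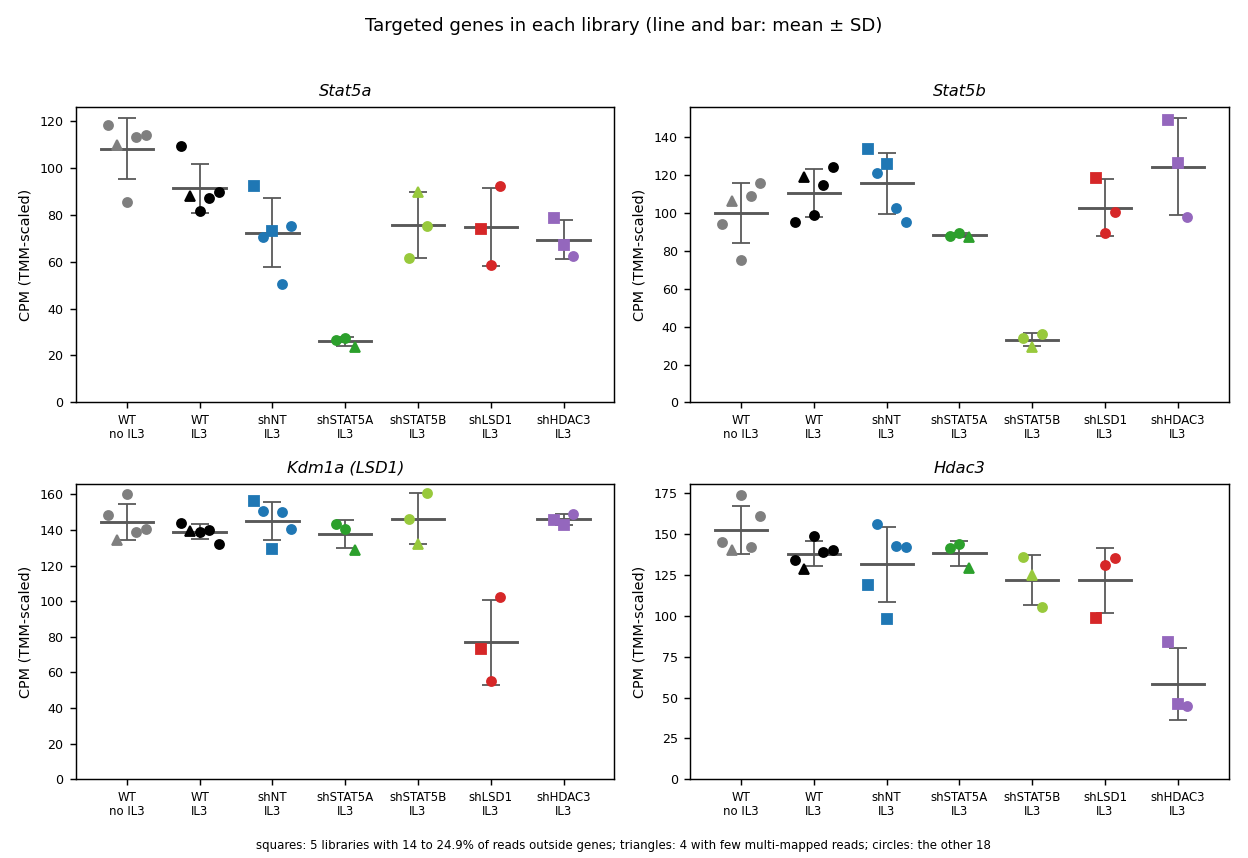
CPM (y axis) of the targeted genes Stat5a, Stat5b, Kdm1a and Hdac3 in each library, by group (x axis), with line and bar for mean ± SD. Squares, triangles and circles mark the library classes, and each gene is lowest in the cells with its own hairpin.

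The wild-type comparison asked which transcripts respond within 30 min of IL3 after deprivation. Among feedback inhibitors of cytokine signalling, Cish (chromosome 9, 107296026 to 107302784) rose from 16.9 ± 4.42 to 483 ± 80.3 CPM (SD, n = 5 each). Socs1 rose from 1.21 ± 0.375 to 186 ± 28.3 and Socs3 from 5.86 ± 1.15 to 359 ± 206, while Socs2 did not pass the main test. Osm, which encodes the cytokine oncostatin M, rose from 10.9 ± 1.91 to 1618 ± 265 CPM. The survival kinase gene Pim1 rose from 15.1 ± 5.83 to 338 ± 21.7 CPM, and Myc, a driver of growth, from 112 ± 40.0 to 1263 ± 151. Egr2, an immediate early zinc finger factor, showed the largest rise, from 0.437 ± 0.201 to 167 ± 47.2 CPM. Cxcr4, a chemokine receptor, fell from 660 ± 97.0 to 173 ± 76.6 CPM, and Ddit4, an inhibitor of mTOR signalling, from 85.7 ± 18.6 to 26.3 ± 11.6.

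In all, 461 of 12073 genes changed with IL3 by edgeR, 362 higher and 99 lower, and 258 of them at least 2-fold (217 higher, 41 lower). The log2 fold change was 8.54 for Egr2 (SE 0.60, adjusted p = 4.93e-10), 7.27 for Socs1 (SE 0.49, adjusted p = 3.08e-10), 7.22 for Osm (SE 0.60, adjusted p = 1.04e-08) and 4.83 for Cish (SE 0.29, adjusted p = 5.53e-11). It was 5.93 for Socs3, 4.48 for Pim1, 3.49 for Myc, 3.69 for Id1 and 1.65 for Egr1, which stayed at 1.55 ± 0.358 CPM after IL3. Fos rose by a log2 fold change of 7.71, to 198 ± 242 CPM, with 630 CPM in stimulated replicate 1 and 72.5 to 107 in the other 4. Cd69, Fosb and Phlda1 completed the largest rises (log2 fold change 5.36, 5.24 and 4.85). Falls included Cxcr4 (-1.93, adjusted p = 0.00991), Zscan2 (-1.91), Ddit4 (-1.70), the G protein regulator Rgs2 (-1.70), Snx32 (-1.58), Esyt3 (-1.54), Tsc22d3 (-1.48) and Kif5a (-1.43). Within the core set, Socs2 stood at 45.3 against 35.6 CPM (adjusted p = 0.295), Bcl2l1 at 49.3 against 36.6 (adjusted p = 0.569) and Ccnd2 at 84.0 against 68.7 (adjusted p = 0.676). With the replicate number as a block in wild type, Socs2 (log2 fold change 0.35, adjusted p = 0.00997) and Bcl2l1 (0.42, adjusted p = 0.0462) passed and Ccnd2 (0.32, adjusted p = 0.0667) did not; over all alternatives their adjusted p reached 0.535, 0.875 and 0.995.

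**Figure D3:**
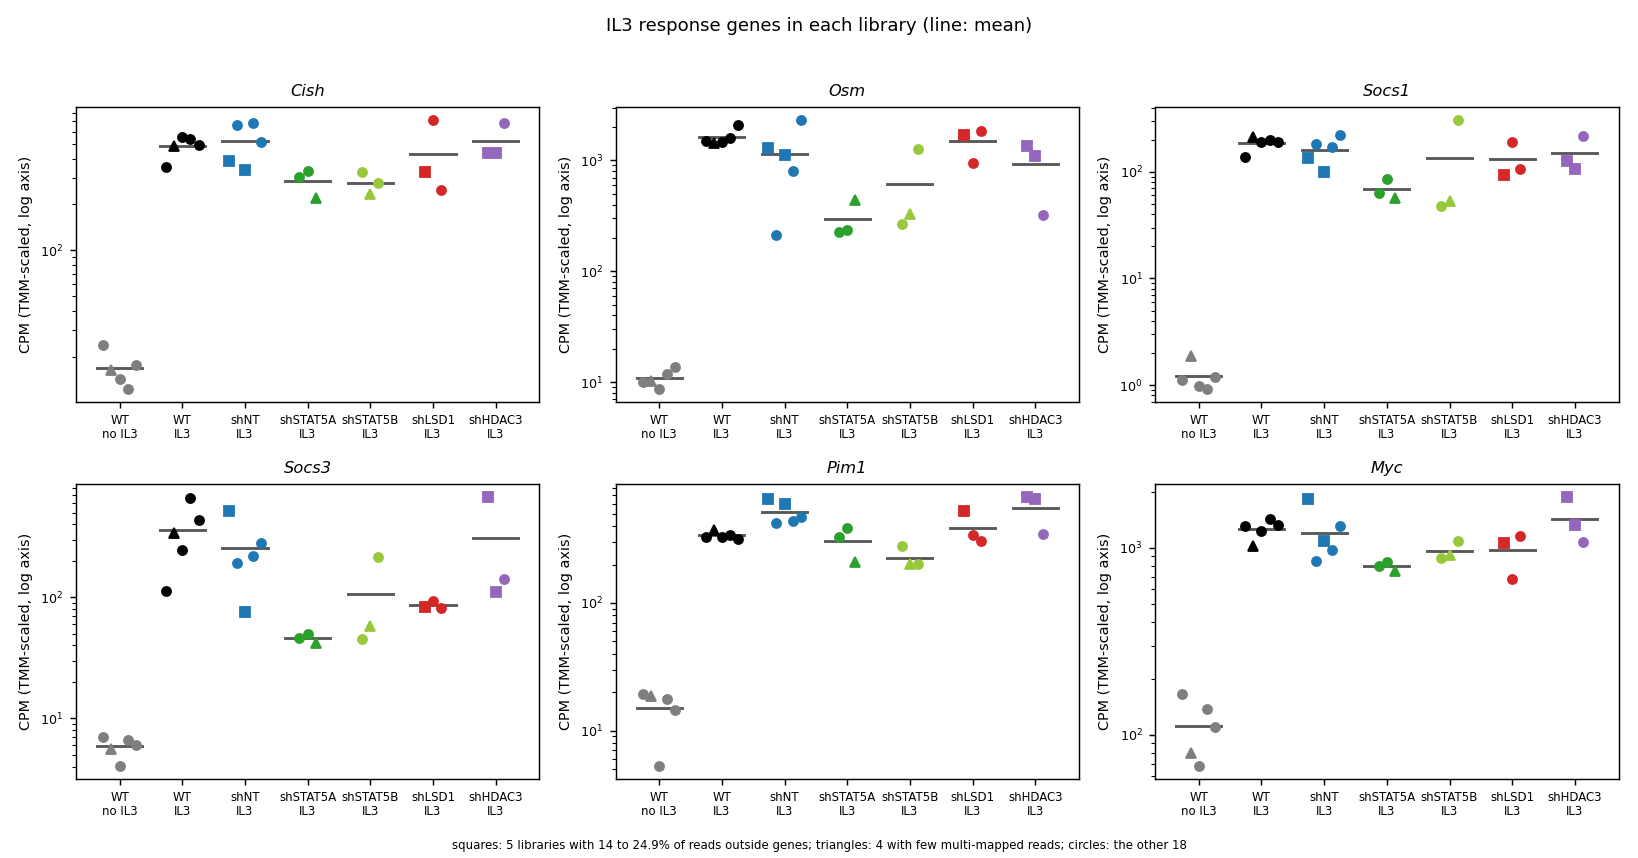
CPM (y axis, log scale) of IL3-responsive genes in each library, by group (x axis), with a line at each mean. The wild-type libraries taken 30 min after IL3 lie above the deprived ones for the induced genes, and the hairpin libraries, all stimulated, also lie above the deprived ones, with Socs3 and Osm lowest on average in the STAT5A knockdown.

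By list, 32 of 38 measured immediate early genes rose with IL3 and 0 fell (33 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 3.23. They included Maff (from 2.59 to 43.6 CPM, adjusted p = 6.89e-12) and Csrnp1 (from 7.88 to 181 CPM). Of 21 STAT5 targets, 10 rose (11 adjusted over the list alone), with a median log2 fold change of 1.18. Both lists passed camera also with an estimated correlation (adjusted p = 1.1e-08 and 6.54e-08). Of 23 p53 targets, 6 rose and 1 fell (6 and 2 adjusted over the list alone); they included the cell cycle inhibitor Cdkn1a (from 203 ± 34.1 to 885 ± 201 CPM), Btg2 (from 14.0 to 277 CPM), Plk3 and Mdm2. Camera gave this list an adjusted p = 0.00319, and adjusted p = 0.108 with an estimated correlation. Of 37 ribosome biogenesis genes, 4 rose (4 adjusted over the list alone), namely Gnl3, Rrs1, Tsr1 and Ddx21 (log2 fold change 1.22, 1.16, 1.06 and 0.75). That list gave adjusted p = 0.00733, and adjusted p = 0.926 with an estimated correlation. None of 80 ribosomal protein genes passed alone, over all genes or adjusted over the list alone, but 79 had negative log2 fold changes (median -0.32, adjusted p = 3.12e-06, and adjusted p = 0.926 with an estimated correlation). Of 17 erythroid or megakaryocyte markers, only Gfi1b, a repressor that recruits LSD1, fell (0 rose and 1 fell adjusted over the list alone), from 147 ± 13.5 to 59.0 ± 34.9 CPM (list adjusted p = 0.00733, and adjusted p = 0.736 with an estimated correlation).

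Several lists held called members without passing camera. In the BCL2 family, Mcl1, which blocks apoptosis, rose from 264 ± 24.3 to 600 ± 36.5 CPM (log2 fold change 1.18, adjusted p = 2.42e-08), and the apoptosis inducer Bbc3 fell from 74.7 ± 13.4 to 38.3 ± 19.0 CPM (adjusted p = 0.0222). The list had 1 member higher and 1 lower among 14, with the same counts adjusted over the list alone. Among 18 NF-kB targets, Nfkbiz and Tnf rose (log2 fold change 2.79 and 2.85), and the pathway inhibitors Nfkbia and Tnfaip3 fell (-1.88 and -1.62), again with the same 2 and 2 adjusted over the list alone. Atf4 (from 161 to 390 CPM), the glucose transporter gene Slc2a1 (log2 fold change 1.14), Bhlhe40 (1.64), Il4ra (2.22) and Il6 (1.94) also rose.

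The count of IL3-responsive genes was 427 within the common class (n = 4 against 4). Because replicate numbers paired the wild-type libraries, they were also fitted with the number as a block, which gave 2569 genes (1523 higher, 1046 lower; 460 of the 461). It moved by over 1.5 times with only the 2 groups fitted (1172), DESeq2 (698), a term for library class (978), without the 5 libraries (874), a threshold of 0.01 (252) and without stimulated replicate 4 (302).

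The no-target hairpin was set against stimulated wild type as a background for the knockdowns. The groups differ in transduction and selection and also in library class, since 2 of 5 no-target and 0 of 5 wild-type libraries had many reads outside genes, and the comparison does not separate these. None of the 12073 genes was called by edgeR, although 2042 had an unadjusted p under 0.05. DESeq2 called 122 genes, and edgeR on the 2 groups alone 31. Genes of glycolysis and hypoxia were higher as a list (median log2 fold change 0.28; 0 called, 4 higher adjusted over the list alone; adjusted p = 0.000157, and adjusted p = 0.873 with an estimated correlation). Ribosomal protein genes (-0.35) and endoplasmic reticulum stress genes (-0.18; 2 lower adjusted over the list alone) were lower, with adjusted p = 8.04e-06 and 0.0156 by camera, and adjusted p = 0.873 for both with an estimated correlation. The IL3-induced score was 4.39 ± 0.16 with the hairpin and 4.39 ± 0.27 in wild type.

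With STAT5A lowered, few genes passed the test in IL3-stimulated cells. Clec4e, a C-type lectin receptor of myeloid cells, stood at 330 ± 102 CPM (SD, n = 3) against 127 ± 33.3 (SD, n = 5), and the growth arrest gene Gadd45a at 70.4 ± 46.7 against 21.7 ± 5.42. B4galnt4 (chromosome 7, 141061104 to 141072400), a glycosyltransferase gene, fell from 11.5 ± 2.23 to 4.10 ± 1.07 CPM. The IL3-induced genes Cish, Osm and Socs3 were lower on average without passing the test: Cish stood at 285 ± 58.4 against 519 ± 158 CPM, Osm at 299 ± 118 against 1147 ± 767, and Socs3 at 45.9 ± 4.04 against 256 ± 162.

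In total, 6 genes were higher and 2 lower with STAT5A lowered, and 1016 had an unadjusted p under 0.05. The log2 fold change was 1.38 for Clec4e (SE 0.22, adjusted p = 0.00943), 1.70 for Gadd45a (SE 0.30, adjusted p = 0.0214), 4.83 for the annexin gene Anxa3 (SE 0.93, adjusted p = 0.0459) and -1.49 for B4galnt4 (SE 0.21, adjusted p = 0.00111). Anxa3 stood at 13 ± 17.7 against 0.488 ± 0.857 CPM, with 2.57 ± 1.86 in stimulated wild type. Cd14, a co-receptor of myeloid cells, reached 42.7 CPM in replicate 3 against at most 0.592 in the controls, and its range overlapped theirs (mean 14.4 ± 24.4, adjusted p = 0.0459). Log2 fold changes of genes that did not pass were -0.86 for Cish (adjusted p = 0.520), -1.94 for Osm (adjusted p = 0.333), -2.48 for Socs3 (adjusted p = 0.232), -1.24 for Socs1 (adjusted p = 0.521), -0.76 for Pim1 (adjusted p = 0.566) and -0.59 for Myc (adjusted p = 0.566).

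STAT5 targets were lower as a list in the STAT5A knockdown (median log2 fold change -0.31, 14 of 21 negative; 0 called, 5 lower adjusted over the list alone; adjusted p = 0.00177). The call was lost at adjusted p = 0.146 with an estimated correlation. Myeloid markers were higher (median 0.73, 25 of 28 positive; 1 called, 8 higher adjusted over the list alone; adjusted p = 1.02e-07, and adjusted p = 0.248 with an estimated correlation). All 80 ribosomal protein genes had positive values (median 0.46; 0 called either way; adjusted p = 1.67e-14, and adjusted p = 0.577 with an estimated correlation). Immediate early genes (-0.32), ribosome biogenesis (-0.18), S phase (-0.15) and endoplasmic reticulum stress genes (0.21) also passed camera, with 0 members called over all genes or adjusted over the list alone. Their adjusted p was 0.0104, 0.00645, 0.00152 and 0.0312, and adjusted p = 0.388, 0.665, 0.577 and 0.577 with an estimated correlation. The number of changed genes was 0 with only the 2 groups fitted, 32 with DESeq2 (7 of the 8), 3 with a term for class and 2 without the 5 libraries. Within the common class (n = 2 against 3) it was 6, with 1 higher and 5 lower, against 6 higher and 2 lower over all libraries. It was 2 without no-target replicate 1 or 5, 3 without its replicate 3 or 4, and 13 without its replicate 2. Anxa3, Gadd45a and Clec4e no longer passed without replicate 3 (log2 fold change 2.59, 1.00 and 1.10), a library with few multi-mapped reads.

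With STAT5B lowered, 41 genes passed the test. Bhlhe40, a transcriptional repressor, fell from 244 ± 104 to 62.4 ± 28.0 CPM (SD, n = 5 and 3), Iqgap2, a scaffold protein gene, from 336 ± 182 to 89.8 ± 24.4, and the Polycomb gene Bmi1 from 82.4 ± 17.7 to 39.8 ± 7.19. Rbm28, a nucleolar RNA-binding protein gene, fell from 125 ± 23.5 to 67.3 ± 3.55 CPM and B4galnt4 from 11.5 ± 2.23 to 4.14 ± 0.988. Gadd45a rose from 21.7 ± 5.42 to 55.0 ± 10.0 CPM and Anxa3 from 0.488 ± 0.857 to 15.2 ± 11.8. Stimulated wild type was below the no-target level for Bhlhe40 (112 ± 9.62 CPM) and Iqgap2 (177 ± 19.3) and above it for Anxa3 (2.57 ± 1.86). Set beside wild type, the shifts of these genes are therefore smaller. Rbm28, B4galnt4 and Gadd45a were closer to the no-target level in wild type, at 123 ± 2.51, 8.65 ± 0.949 and 29.1 ± 9.46 CPM. None of these genes passed between the no-target hairpin and wild type. Pim1 stood at 227 ± 45.0 against 519 ± 103 CPM and Cish at 278 ± 45.1 against 519 ± 158, neither past the threshold.

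In total, 25 genes were higher and 16 lower, and 1925 had an unadjusted p under 0.05. The log2 fold change was -1.97 for Bhlhe40 (SE 0.43, adjusted p = 0.0453), -1.90 for Iqgap2 (SE 0.41, adjusted p = 0.0415), -1.45 for B4galnt4 (SE 0.21, adjusted p = 0.00119), -1.05 for Bmi1 (SE 0.22, adjusted p = 0.0339) and -0.89 for Rbm28 (SE 0.13, adjusted p = 0.00119). Frmd6 (-1.21) and Abi2 (-0.87) were the other named falls. Rises were 5.06 for Anxa3 (SE 0.94, adjusted p = 0.0220), 2.23 for Gstm1, 2.00 for Rdh12, 1.54 for Dpp7, 1.49 for Slc38a7, 1.41 for Coprs, 1.38 for Dnase2a and 1.34 for Gadd45a (adjusted p = 0.0478). Genes that did not pass were Pim1 (-1.19, SE 0.31, adjusted p = 0.0939), Cish (-0.90, adjusted p = 0.191), Socs3 (-1.27, adjusted p = 0.310), Osm (-0.89, adjusted p = 0.392) and Myc (-0.33, adjusted p = 0.507).

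STAT5 targets were lower as a list in the STAT5B knockdown too (median log2 fold change -0.37, 17 of 21 negative; 0 called, 3 lower adjusted over the list alone; adjusted p = 0.00102, and adjusted p = 0.0973 with an estimated correlation). Myeloid markers were higher (median 1.08, 24 of 28 positive; 1 called, 11 higher adjusted over the list alone; adjusted p = 6.84e-09, and adjusted p = 0.211 with an estimated correlation), among them the lysozyme gene Lyz2, at 13 ± 2.78 against 5.59 ± 1.13 CPM (adjusted p = 0.0453). Ribosomal protein genes had a median of 0.46 and mitosis genes of -0.12 (0 called either way; adjusted p = 7.36e-10 and 0.0394, and adjusted p = 0.612 and 0.587 with an estimated correlation). The number of changed genes was 1 with only the 2 groups fitted, 163 with DESeq2 (40 of the 41), 17 with a term for class, 11 without the 5 libraries and 5 within the common class (n = 2 against 3). It ranged from 7 without replicate 3 to 213 without replicate 1; without no-target replicate 4, 1 or 3 it was 8, 9 or 10, without replicate 2 it was 13, and without no-target replicate 5 it was 23.

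Compared directly, the STAT5A and STAT5B knockdowns differed in 3 genes by edgeR (409 at an unadjusted p under 0.05). Stat5a (log2 fold change -1.54) and Stat5b (1.42) followed their hairpins, each with adjusted p = 0.000222. Vps26b, part of the retromer complex, stood at 119 ± 3.68 CPM in the STAT5A and 73.8 ± 11.1 in the STAT5B knockdown (SD, n = 3 each; log2 fold change 0.69, adjusted p = 0.0110). Cholesterol synthesis genes were lower in the STAT5A than in the STAT5B knockdown as a list (median -0.20; 0 called either way; adjusted p = 0.0396, and adjusted p = 0.658 with an estimated correlation). DESeq2 called 13 genes and the fit of the 2 groups alone 0; within the common class (n = 2 each) 4 were called, 6 were called with a replicate block, with a term for class or without STAT5B knockdown replicate 1, and 9 without STAT5A knockdown replicate 3.

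The IL3-responsive sets from wild type asked how far the knockdowns shift the levels of these genes after IL3. All hairpin libraries were stimulated, so a changed response cannot be told from a changed level before IL3. The 217 induced genes had negative medians with STAT5A lowered (log2 fold change -0.19, 151 negative and 66 positive), STAT5B lowered (-0.19, 154 and 63) and LSD1 lowered (-0.29, 167 and 50), with 0, 1 and 0 members called lower. The 41 repressed genes had positive medians in the same 3 knockdowns (0.18, 0.21 and 0.29, with 31, 31 and 33 positive), with 0, 0 and 1 members called higher. These shifts passed camera with a preset correlation, and none passed with an estimated correlation. With HDAC3 lowered, the induced set had a median of 0.07 with 127 positive, and the repressed set a median of 0.08 but a mean of -0.09. For scale, IL3 itself moved the induced score from 2.37 ± 0.11 to 4.39 ± 0.27 on the log2 scale. Against 4.39 ± 0.16 with the no-target hairpin, the induced score was 4.2 ± 0.07, 4.19 ± 0.04, 4.13 ± 0.18 and 4.44 ± 0.23 in the STAT5A, STAT5B, LSD1 and HDAC3 knockdowns (SD, n = 3 each).

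Camera gave the induced set an adjusted p = 0.000972 for STAT5A, 0.00666 for STAT5B, 6.65e-09 for LSD1 and 0.170 for HDAC3, and the repressed set 0.000863, 0.0136, 5.52e-06 and 0.561. With an estimated correlation none of the 8 passed (adjusted p = 0.471, 0.471, 0.251 and 0.728 for the induced and 0.421, 0.471, 0.251 and 0.815 for the repressed set). The exact two-sided permutation test of the induced score gave p = 0.143, 0.107, 0.0893 and 0.786 (0.229, 0.214, 0.214 and 0.786 adjusted over the 8 scores), where the smallest p possible is 0.0179. Within the common class, the induced medians were -0.19, -0.19, -0.35 and -0.18 for STAT5A, STAT5B, LSD1 and HDAC3. Within the class with many reads outside genes they were -0.21 for LSD1 (n = 1 against 2) and 0.19 for HDAC3 (n = 2 against 2), so the sign for HDAC3 differed between the classes, with n = 1 against 3 in the common class. Without the 5 libraries, the HDAC3 median was -0.18 (adjusted p = 0.0490), but it rests on 1 HDAC3 knockdown library there, as within the common class.

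**Figure D4:**
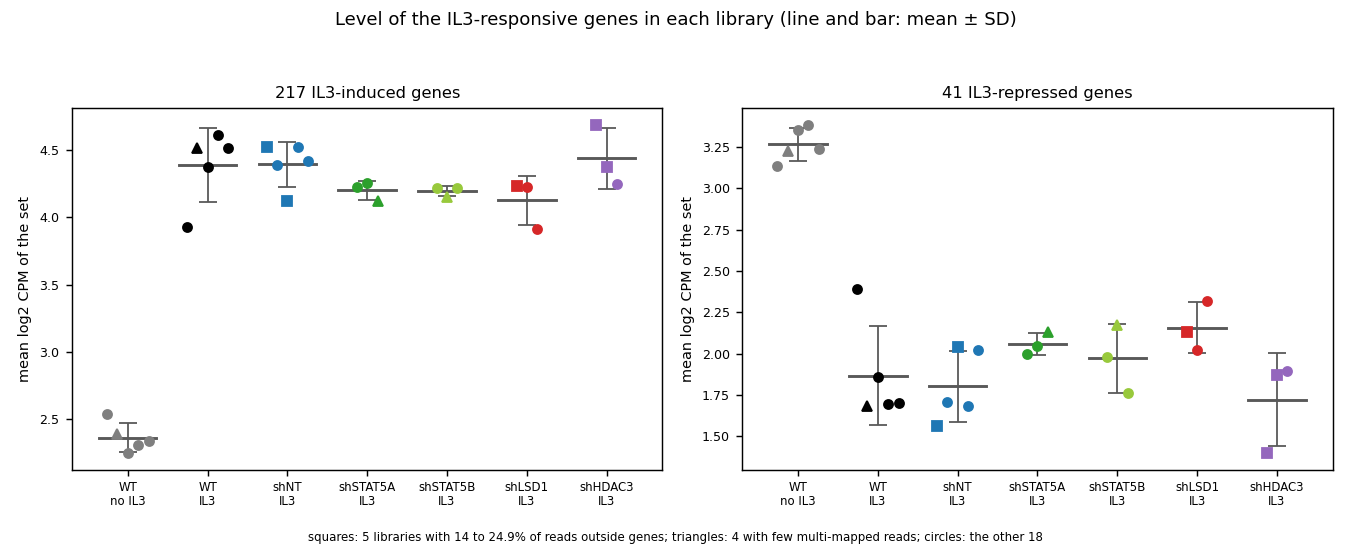
Mean log2 CPM (y axis) of the 217 IL3-induced and the 41 IL3-repressed genes in each library, by group (x axis), with line and bar for mean ± SD. The hairpin groups lie within 4.13 to 4.44 on the induced score, close to stimulated wild type at 4.39 and far from deprived wild type at 2.37.

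With LSD1 lowered, a small group of genes was higher, several of them low in control cells. Gfi1b (chromosome 2, 28609450 to 28621982) rose from 36.3 ± 19.2 CPM (SD, n = 5) to 258 ± 162 (SD, n = 3). Slc15a3 (chromosome 19, 10839727 to 10859362), a lysosomal peptide transporter gene, rose from 0.548 ± 0.123 to 47.5 ± 65.2 CPM, and Alox15 (chromosome 11, 70344152 to 70352031), a lipoxygenase gene, from 0.171 ± 0.236 to 38.0 ± 51.3. Pilra, an inhibitory receptor gene of myeloid cells, rose from 0.695 ± 0.304 to 19.7 ± 21.5 CPM. Csf1, the macrophage growth factor gene, rose from 27.9 ± 14.1 to 145 ± 120 CPM, and Milr1, an inhibitory receptor gene of mast cells, from 2.84 ± 2.11 to 44.9 ± 55.8. Milr1 also stood at 15.7 to 18.8 CPM with STAT5B lowered and at 45.6 in STAT5A knockdown replicate 3 (at most 6.16 in the controls). Csf1 spanned 44.1 to 130 CPM with STAT5A lowered and 37.7 to 66.1 with STAT5B lowered (at most 52.7 in the controls). High levels of these genes were thus not particular to LSD1, while Gfi1b stayed within the control range in both STAT5 knockdowns.

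In total, 19 genes were higher and 1, Kdm1a, lower, and 810 had an unadjusted p under 0.05. The log2 fold change was 8.05 for Alox15 (SE 1.00, adjusted p = 0.000171), 6.4 for Slc15a3 (SE 0.76, adjusted p = 0.000157), 4.83 for Pilra (SE 0.65, adjusted p = 0.000356) and 2.83 for Gfi1b (SE 0.37, adjusted p = 0.000251). It was 4.00 for Milr1, 2.38 for Csf1 and 2.35 for Pi16. The 3 LSD1 knockdown libraries spanned 1.38 to 96.6 CPM for Alox15, 3.94 to 122 for Slc15a3 and 154 to 445 for Gfi1b, and each was above every control. Among IL3-induced genes that did not pass, Socs3 stood at 86.4 ± 6.32 against 256 ± 162 CPM (adjusted p = 0.562) and Pim1 at 389 ± 116 against 519 ± 103 (adjusted p = 0.967). Il2ra stood at 3.70 ± 3.42 against 0.213 ± 0.316 CPM (log2 fold change 4.2, adjusted p = 0.129).

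**Figure D5:**
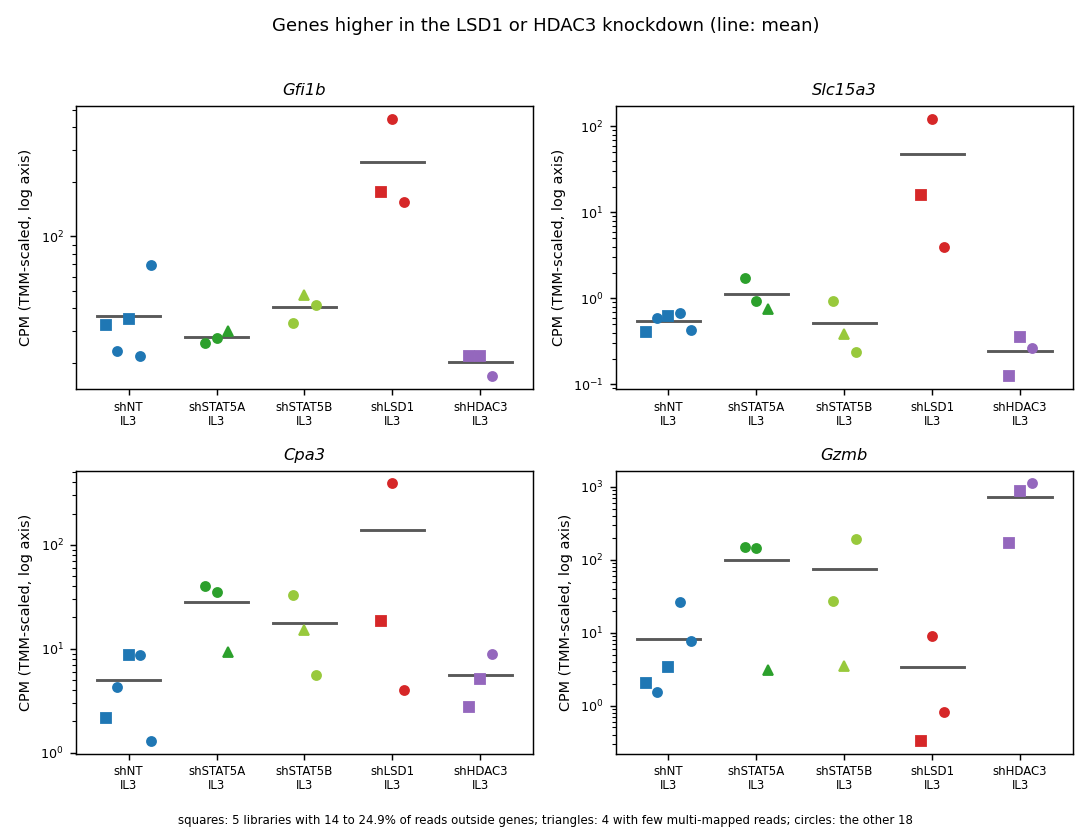
CPM (y axis, log scale) of Gfi1b, Slc15a3, Cpa3 and Gzmb in each library of the 5 hairpin groups (x axis), with a line at each mean. Gfi1b and Slc15a3 lie above every control in all 3 LSD1 knockdown libraries, Cpa3 is far above the controls in 1 of them, and Gzmb is highest in the HDAC3 knockdown.

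Markers of mast cells or basophils were higher as a list with LSD1 lowered (median log2 fold change 1.20, 15 of 17 positive; 2 called, 5 higher adjusted over the list alone; adjusted p = 2.51e-07). That call was lost at adjusted p = 0.148 with an estimated correlation. The mast cell carboxypeptidase gene Cpa3 stood at 138 ± 219 CPM against 5.01 ± 3.51 (adjusted p = 0.0279), and the cytokine gene Il13 at 14.4 ± 24.1 against 0.290 ± 0.190 (adjusted p = 0.0195), both with ranges that overlapped the controls. Myeloid markers were higher too (median 0.63; 0 called, 4 higher adjusted over the list alone; adjusted p = 1.09e-09, and adjusted p = 0.148 with an estimated correlation). Ribosome biogenesis genes were lower (median -0.38, 34 of 37 negative; adjusted p = 8.51e-07, and adjusted p = 0.376 with an estimated correlation), as were mitosis genes (-0.16, 28 of 29 negative), immediate early genes (-0.28) and glycolysis and hypoxia genes (-0.12), with 0 members called over all genes or adjusted over the list alone in these 4. The last 3 gave adjusted p = 0.000159, 0.000714 and 0.0260, and adjusted p = 0.159, 0.159 and 0.549 with an estimated correlation. Endoplasmic reticulum stress (0.24), NF-kB target (0.32) and amino acid stress genes (0.10) were higher, with 0 called, 2, 0 and 1 adjusted over the list alone, and adjusted p = 0.000112, 0.0338 and 0.0338. With an estimated correlation these gave adjusted p = 0.209, 0.185 and 0.506. Co-repressor genes (-0.09, Gfi1b higher and Kdm1a lower) and erythroid or megakaryocyte markers (0.12, Gfi1b higher) had the same counts adjusted over the list alone, adjusted p = 0.0305 and 0.0338, and adjusted p = 0.159 and 0.506 with an estimated correlation.

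Alox15, Slc15a3, Pilra and Gfi1b no longer passed when only the 2 groups were fitted, where 0 genes were called, and passed with every library left out in turn. Milr1, Csf1, Pi16, Il13 and Cpa3 no longer passed without LSD1 knockdown replicate 2, with log2 fold changes of 2.17, 1.45 and 1.12 for Milr1, Csf1 and Cpa3. The number of changed genes was 64 with DESeq2 (all 20 among them), 5 without the 5 libraries, 2 within the common class (n = 2 against 3) and 0 within the other class (n = 1 against 2). Left out in turn, LSD1 knockdown replicate 2 or 3 gave 5 or 60 genes, and no-target replicate 5, 1 or 4 gave 7, 8 or 9.

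With HDAC3 lowered, 3 genes passed the test by edgeR (687 at an unadjusted p under 0.05): Hdac3 was lower, and 2 granzyme genes of cytotoxic granules were higher. Gzmb (chromosome 14, 56258838 to 56262260) stood at 717 ± 491 CPM (SD, n = 3) against 8.28 ± 10.6 (SD, n = 5), a log2 fold change of 6.35 (SE 1.11, adjusted p = 0.0255). Gzmc, chosen after its values were seen, stood at 8.34 ± 7.39 against 0.0288 ± 0.0644 CPM (adjusted p = 0.0255). Of the IL3-responsive genes, Cish stood at 518 ± 140 against 519 ± 158 CPM (adjusted p = 0.999), Pim1 at 557 ± 182 against 519 ± 103 (adjusted p = 0.946) and Myc at 1423 ± 409 against 1208 ± 382 (adjusted p = 0.883).

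All 29 S phase genes had positive log2 fold changes with HDAC3 lowered (median 0.25; 0 called, 1 higher adjusted over the list alone; adjusted p = 2.04e-09, and adjusted p = 0.407 with an estimated correlation). Ribosome biogenesis genes were higher (0.33, 31 of 37 positive; 0 called either way; adjusted p = 8.9e-06, and adjusted p = 0.497 with an estimated correlation). Genes of glycolysis and hypoxia were lower (-0.47, 23 of 29 negative; 0 called, 1 lower adjusted over the list alone; adjusted p = 2.03e-05, and adjusted p = 0.497 with an estimated correlation). Myeloid markers (-0.63), interferon response genes (-0.15) and ribosomal protein genes (-0.12) were lower with 0 called either way. Their adjusted p was 0.00746, 0.00746 and 0.00787, and adjusted p = 0.497, 0.497 and 0.835 with an estimated correlation. Of the 3 HDAC3 knockdown libraries, 2 had many reads outside genes; the number of changed genes was 8 without the 5 such libraries (n = 1 against 3), 6 with a term for class, and 5 within the common class. It was 0 with only the 2 groups fitted or with a replicate block, 10 with DESeq2, 9 without replicate 1, 0 without replicate 2 or 3 or no-target replicate 2, and 1 without no-target replicate 1, 3 or 5.

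LSD1 and HDAC3 knockdowns, compared directly, differed in 99 genes (77 higher and 22 lower with LSD1 lowered; 1719 at an unadjusted p under 0.05). Higher with LSD1 than with HDAC3 lowered were the eosinophil granule genes Epx, at 1084 ± 579 against 26.5 ± 24.1 CPM (SD, n = 3 each; log2 fold change 5.38, adjusted p = 0.0194), and Prg2, at 783 ± 930 against 17.7 ± 7.38 (5.48, adjusted p = 0.0128), with Ear6 (6.08) and Prg3 (5.58). Ms4a3, a granulocyte progenitor gene, stood at 448 ± 142 against 44.6 ± 17.2 CPM (adjusted p = 0.00679). With the no-target hairpin, Epx stood between these at 198 ± 215, Prg2 at 175 ± 186 and Ms4a3 at 115 ± 66.8 CPM (SD, n = 5), and none of the 3 passed in either knockdown against it. Prg2 stood at 246, 1857 and 247 CPM in the LSD1 knockdown libraries and at 9.84 to 24.5 in those of HDAC3. It also varied between wild-type libraries, from 93.9 to 581 CPM in deprived and from 75.5 to 505 in stimulated cells. Values of 246 and 247 lie within that spread, 1857 above it and those of HDAC3 below it. Differences between cultures in this gene were not tested. Slc15a3 (7.58, adjusted p = 0.00141), Gfi1b (3.68, adjusted p = 0.000421), Gadd45a (2.02) and the receptor genes Ifngr2 (1.39) and Il2rb (2.30) were higher as well. Gzmb was lower with LSD1 lowered (-7.66, adjusted p = 0.0130), as were Pprc1 (-1.72), a regulator of mitochondrial biogenesis, Kctd15 (-1.47), Txk (-1.43), Lfng (-1.31), Repin1 (-0.72) and Uhrf1 (-0.70), which maintains DNA methylation.

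By list, myeloid markers were higher with LSD1 lowered than with HDAC3 lowered (median 1.52, 26 of 28 positive; 2 called, 11 higher adjusted over the list alone; adjusted p = 9.06e-10, and adjusted p = 0.184 with an estimated correlation). Ribosome biogenesis genes were lower (-0.75, 33 of 37 negative; 1 called, Nop56, and 18 lower adjusted over the list alone; adjusted p = 1.29e-10, and adjusted p = 0.345 with an estimated correlation). All 29 S phase genes had negative values (-0.34; 1 called, 2 lower adjusted over the list alone; adjusted p = 2.17e-07, and adjusted p = 0.299 with an estimated correlation). Mast cell or basophil markers had a median of 2.01 (1 higher, Hdc, and 1 lower, Gzmb; 7 and 2 adjusted over the list alone; adjusted p = 0.0174, and adjusted p = 0.435 with an estimated correlation). Co-repressor (-0.24), immediate early (-0.27) and mitosis genes (-0.12) were lower, and ribosomal protein (0.23), interferon response (0.14) and endoplasmic reticulum stress genes (0.18) higher. Adjusted over the list alone, these 6 had 2 higher and 2 lower, 0, 0, 0, 2 higher and 4 higher, and over all genes 2 higher and 1 lower for co-repressor genes and 0 for the rest. Their adjusted p was 0.0222, 0.0288, 0.0315, 0.01, 0.0288 and 0.0222, and adjusted p = 0.184, 0.435, 0.443, 0.831, 0.435 and 0.481 with an estimated correlation. The number of changed genes was 0 with only the 2 groups fitted, 332 with DESeq2 (all 99 among them) and 198 with a term for class. Without the 5 libraries or within the common class it would rest on 1 HDAC3 knockdown library. It was 409 without LSD1 knockdown replicate 1, 7 without its replicate 2, and 21, 56 or 25 without HDAC3 knockdown replicate 1, 2 or 3.

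Effects of the STAT5A and STAT5B knockdowns correlated positively across genes. Those of the HDAC3 knockdown correlated negatively with both, and at -0.03 and -0.05 with a term for library class. Unchanged groups with shared controls gave 0.38 and 0.37 in simulations without class. A value near 0 with shared controls therefore need not mean that the effects are unrelated. Across 12073 genes, log2 fold changes of the STAT5A and STAT5B knockdowns correlated at r = 0.74 (Spearman rho 0.73), against 0.39 in simulations of unchanged groups with shared controls. Their covariance of 0.169 exceeded the simulated 0.0487 by 0.121. LSD1 effects correlated at 0.41 with STAT5A and 0.35 with STAT5B effects, near the simulated 0.39 and 0.38, and at -0.03 with HDAC3 effects. HDAC3 effects correlated at -0.35 with STAT5A and -0.32 with STAT5B effects, where the simulations gave 0.38 and 0.37, and 0.37 for LSD1 with HDAC3. Genes are not independent replicates, so these values carry no p. The simulations leave out library class, which was uneven between groups. Many reads outside genes were found in 2 of 3 HDAC3, 1 of 3 LSD1 and 2 of 5 no-target libraries, and in 0 STAT5A or STAT5B knockdown libraries. With the controls divided between the 2 knockdowns, r was 0.41 for STAT5A and STAT5B, 0.11 and 0.09 for LSD1 with each, -0.44 and -0.41 for HDAC3 with each, and -0.26 for LSD1 with HDAC3. With a term for class and the controls shared, the 6 values in the same order were 0.56, 0.48, 0.38, -0.03, -0.05 and -0.00. Unchanged groups that differ in class were not simulated to set beside them.

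Genes called in the same direction by a pair of knockdowns were Anxa3 and Gadd45a (higher) and B4galnt4 (lower) for STAT5A and STAT5B, and Pilra (higher) for STAT5A and LSD1. The other pairs shared 0 calls. Independent calls would share 0.0124, 0.00265 and 0.00944 genes, without regard to the shared controls. Across the STAT5A, STAT5B, LSD1 and HDAC3 knockdowns, the log2 fold change of B4galnt4 was -1.49, -1.45, 0.11 and 0.40, that of Gadd45a 1.70, 1.34, 1.07 and -0.96, and that of Pilra 3.29, 1.06, 4.83 and 0.77.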

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

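Set before their results were seen were the test of genomic DNA over all 5 libraries with many reads outside genes and the counts of other splits; the tests of genomic DNA in parts of these libraries, of the knockdown, of T or NK cells, of library class for Gzmb, and of a deciding library, mast cells and basophils for the mast cell markers were chosen only after the result was seen. The splits were run on 2 groups alone before the form with all libraries in the fit was chosen, and receptor genes with reads were counted without equal depth before equal depth was chosen. Over 108 groups of values, 18 held a library far from the others by Dixon's test, where chance alone gives about 1 in 20 groups, or 5%. That rate is only a guide, since the groups of values share libraries. The knockdown groups, with 3 libraries each, were too small for the test and did not enter it.

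In 5 libraries from 3 hairpin groups, 14.0 to 24.9% of reads fell outside genes, and these libraries stand apart from the rest. The knockdown of LSD1 or HDAC3 is argued against as the cause, because 2 no-target control libraries are among the 5 while 2 LSD1 and 1 HDAC3 knockdown libraries are not. Genomic DNA may explain LSD1 knockdown replicate 1, no-target replicate 3 and HDAC3 knockdown replicate 2. With all libraries brought to 5.48 M reads, reads fell there on 345, 94.0 and 107 of 1432 odorant and vomeronasal receptor genes. In the 22 libraries outside this class they fell on 15.1 to 26, so most but not all of these genes are silent in these cells. Genomic DNA is argued against for no-target replicate 1 and HDAC3 knockdown replicate 1, with reads on 21.6 and 21.7 such genes. Their reads outside genes would bring 55.1 and 82.0 at the lowest yield of the other 3. By this later test alone it is argued against as a cause of all 5. The test set beforehand did not decide, as the receptor genes took 1.71 times the usual share of counts over the 5 (median, range 1.07 to 3.88). That share also holds receptor genes that are not silent. Without equal depth, each of the 22 libraries had 374 to 1569 reads on only 21 to 48 of them. What sets no-target replicate 1 and HDAC3 knockdown replicate 1 apart stays open, as do other causes in the other 3. No biological difference other than the hairpin was tested.

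Gzmb was higher in all 3 HDAC3 knockdown libraries, at 169, 866 and 1118 CPM, than in the 5 controls. T or NK cells in the cultures are argued against: Prf1, Klrd1 and Gzma, abundant in such cells, had 0 reads among 25.1 M counted reads, which allows 0.119 CPM (without TMM factors), beside 18994 Gzmb reads, although Klrd1 and Gzma had no reads in any library. An earlier test on the share of T and NK markers, at most 5.29% of Gzmb in these libraries, did not decide and was replaced, with these markers together at 33.4 CPM in replicate 3 (at most 13.5 in the controls), Nkg7 at 15.8 (at most 5.09) and Cd3g at 6.85 (at most 1.37) but Cd3e at 0.0878 (at most 0.452). The class with many reads outside genes is argued against as well, since its 3 libraries without the HDAC3 hairpin stood at 0.327 to 3.42 CPM; a fold change within the common class, tested earlier, rests on 1 HDAC3 knockdown library (log2 6.48, adjusted p = 0.0885) and was replaced. An effect of HDAC3 on Gzmb stays a hypothesis, since Gzmb also stood at 149 and 143 CPM in STAT5A knockdown replicates 1 and 2, 194 in STAT5B knockdown replicate 3 and 26.6 in no-target replicate 4, and clonal differences between cultures were not tested.

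Mast cell or basophil markers were higher as a list with LSD1 lowered, with Cpa3 at 390 CPM in replicate 2. Mixed-in mast cells are argued against: Kit and Fcer1a, abundant in mast cells, had 0 reads in that library, which allows 0.194 CPM for the pair (without TMM factors), although 7 and 5 reads over all libraries show that both can be counted. Mixed-in basophils, which need no Kit, stay open, because their markers disagree. Of Fcer1a and Prss34, abundant in such cells, Fcer1a had 0 reads in that library, which goes against them, and Prss34 had 5. On the other side, Cd200r3 stood at 381 CPM (at most 20.1 in the controls), Mcpt8 at 26.6 (at most 19.7) and Ms4a2 at 24.4 (at most 17.0). An earlier test on 6 markers against the control mean and SD did not decide and was replaced. Without replicate 2 the list's median fell from 1.20 to 0.44 and without replicate 1 or 3 it was 1.25 or 1.65, so whether 1 library decides the pattern stays open. A graded effect of LSD1 loss on these genes could also give it and was not tested. High Cpa3 was not particular to LSD1. It spanned 9.21 to 40.1 CPM in the STAT5A and 5.64 to 32.6 in the STAT5B knockdown libraries, against at most 8.71 in the controls.

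With all libraries in the fit, only the real split of the same libraries gave as many genes for the IL3 response (461, at most 89 in 69 other splits drawn). The same was so for the STAT5A knockdown (8, at most 3) and the STAT5B knockdown (41, at most 29). In this form of the fit, that argues against chance for each comparison alone, without adjustment over the comparisons. With 56 splits, the smallest share possible is 0.0179. With only the 2 groups in the fit, the form run earlier, the real split again stood alone for the IL3 response (1172, at most 156 in 99 other splits drawn). It also did for the STAT5B knockdown (1, highest other 0), but that 1 gene is the target Stat5b, which says nothing of other genes. For the STAT5A knockdown that form gave 0 genes, with 112 in the highest other split, so the argument for STAT5A rests on the form chosen later. Of the wild-type splits, the 8 others that part all 5 same-numbered pairs gave at most 16 genes, and those that part fewer gave up to 89. With the real one, 9 such splits were drawn, too few for a share under 0.05. With all libraries in the fit, chance cannot be excluded for the LSD1 knockdown, where 4 of 56 splits gave as many as 20 genes and the highest other 4640. Nor can it for the HDAC3 knockdown, where 10 of 56 gave as many as 3 and the highest other 4158. For the no-target hairpin against wild type the count is 0, so that all 70 splits give as many whatever they hold (highest other 1) and nothing can be said; with only the 2 groups in the fit it was 31, with 3 in the highest other of 100 splits drawn. In the same form, the LSD1 and HDAC3 knockdowns and both comparisons between knockdowns gave 0. The counts of 4640 and 4158 came from splits that put 3 libraries with many reads outside genes in 1 arm, which points to a structure of the samples. Within the common class, 2 genes were called for LSD1 (n = 2 against 3), and HDAC3 is left there with 1 library. For STAT5A against STAT5B knockdown (3 genes, highest other 227, 2 of 10 splits as high) and LSD1 against HDAC3 knockdown (99, highest other 5214, again 2 of 10), the 10 splits are too few for a share under 0.05. The 5214 came from the split that puts the 3 libraries with many reads outside genes together. The common class leaves 1 HDAC3 knockdown library for this comparison, so it cannot serve as a check.

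Some differences between knockdown effects passed a test of the difference itself. STAT5A and STAT5B knockdowns differed in 3 genes, among them the hairpin targets Stat5a and Stat5b, and LSD1 and HDAC3 knockdowns in 99. With only the 2 groups fitted, both counts were 0. Other splits of the same libraries gave up to 227 and 5214 genes, so the counts do not set either difference apart from chance. The IL3-induced set was lower by a median log2 fold change of -0.35 and the IL3-repressed set higher by 0.32 with LSD1 than with HDAC3 lowered (camera p = 2.42e-07 and 0.000281, and 0.102 and 0.154 with an estimated correlation).

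Reads outside genes, data the comparisons did not use, exceeded the range of the no-target controls (10.3 to 17.4%) in HDAC3 knockdown replicate 2 (19.8%) and LSD1 knockdown replicate 1 (24.9%).

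Stimulated wild-type replicate 1 lay apart from the other 4 in 7 measures, where about 1 in 20 is given by chance. Fos stood at 630 CPM (72.5 to 107 in the others), Fosb at 50.3 (23.5 to 27.8), Egr1 at 2.19 (1.37 to 1.43), Ccnd2 at 98.8 (77.3 to 81.4), Gfi1b at 120.3 (36.6 to 52.5) and Socs1 at 138 (190 to 211). Its IL3-repressed score was 2.39 (1.69 to 1.86). Stimulated replicate 2 had 9.18% of reads outside genes (10.2 to 10.6%) and 0.177 multi-mapped reads per counted read (0.250 to 0.265). Osm stood at 2081 CPM in stimulated replicate 5 (1446 to 1602).

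Among deprived wild-type libraries, Stat5a stood at 85.6 CPM in replicate 3 (109 to 118), Socs1 at 1.86 in replicate 2 (0.924 to 1.19) and Gfi1b at 124 in replicate 2 (148 to 157). Among no-target libraries, 15563 genes were detected in replicate 3 (13261 to 13830), and Il2ra stood there at 0.760 CPM (0 to 0.170). Anxa3 stood at 2.01 CPM in no-target replicate 2 (0 to 0.226), Gfi1b at 69.1 in replicate 5 (21.9 to 34.8) and Gzmb at 26.6 in replicate 4 (1.54 to 7.78).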

How the results depend on the processing

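The alternatives with a term for library class, without the 5 libraries with many reads outside genes, with a replicate block in wild type alone, the IL3 scores under other settings, and the mast cell list with each LSD1 replicate left out, were chosen only after the results were seen. The alternatives made 2540 pairs of result and setting over 175 results, and each library was left out only in the comparisons that hold it. Of 51 named IL3-responsive genes, 42 passed the threshold in each setting run for them, among them Cish, Socs1, Osm, Pim1, Myc and Egr2. Fits within a library class are not among these settings. In the common class (n = 4 against 4), 3 of the 42 missed the threshold with log2 fold changes near those of all libraries: Cxcr4 (-1.86 against -1.93, adjusted p = 0.0963), Gnl3 (1.16 against 1.22, adjusted p = 0.0596) and Nfkbia (-1.70 against -1.88, adjusted p = 0.0535). Of the named called genes in the other comparisons, only Stat5b in its own knockdown passed in each setting. The fit of all libraries uses 1 spread per gene for every group. Replicates correlated at r 0.924 to 0.967 for LSD1, 0.935 to 0.971 for HDAC3, 0.935 to 0.987 for no target and 0.955 to 0.975 for STAT5B. For STAT5A this was 0.967 to 0.991 and within wild-type groups 0.965 to 0.991. The fit of only the 2 groups compared lost the other genes. It rests on fewer libraries but called more genes for IL3 (1172 against 461), so fewer libraries alone need not be why. A spread shared with closer replicates of other groups can be too small for hairpin groups that vary more, and then gives too many knockdown calls. Whether it did was not tested. The fit of only the 2 groups also called more genes for the no-target hairpin against wild type (31 against 0). Outside that fit, Stat5a in its own knockdown, B4galnt4 in both STAT5 knockdowns, Rbm28 with STAT5B lowered, Alox15, Slc15a3, Pilra and Gfi1b with LSD1 lowered, and Stat5a and Stat5b between the STAT5 knockdowns passed in the other settings. Within the common class, with fewer libraries, B4galnt4 with STAT5A lowered (log2 fold change -1.20, adjusted p = 0.145), Rbm28 (-0.67, 0.0672), Alox15 (8.75, 0.0513), Gfi1b (2.97, 0.0721) and Stat5a between the STAT5 knockdowns (-1.33, 0.05003) missed the threshold. RLE factors moved no count of changed genes by over 1.5 times and no median of all genes by over 0.0156. Depth was lowest in the libraries with many reads outside genes (5.48 to 7.53 M reads), and on simulated data 44 to 60% of 2-fold changes were recovered in the comparisons with arms of 3, so that smaller effects can be missed there. Where no reason is given, the cause was not tested.

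Numbers of changed genes that moved by over 1.5 times were as follows. With only the 2 groups fitted they were 1172 for IL3 (453 of the 461 among them), 0 for STAT5A, 1 for STAT5B, 0 for LSD1, 0 for HDAC3, 31 for the no-target hairpin, 0 for STAT5A against STAT5B and 0 for LSD1 against HDAC3. With DESeq2 they were 698, 32, 163, 64, 10, 122, 13 and 332 in the same order, and held all 461, 7 of 8, 40 of 41, all 20, 2 of 3, 3 of 3 and all 99 of the genes called where there were any. With no filter, which adds genes to the adjustment, they were 4 for STAT5A, 18 for STAT5B and 50 for LSD1 against HDAC3. At a threshold of 0.01 they were 252 for IL3, 3 for STAT5A, 4 for STAT5B, 6 for LSD1, 0 for HDAC3 and 7 for LSD1 against HDAC3, and with a log2 fold change of at least 1 they were 258 for IL3. A replicate block gave 3 for STAT5A, 8 for LSD1, 0 for HDAC3 and 6 for STAT5A against STAT5B, and changed no other count by over 1.5 times; the replicate numbers paired no more than 2 of 3 libraries there, and the block with the wild-type libraries only, where all 5 paired, gave 2569 for IL3. With a term for class they were 978 for IL3, 3 for STAT5A, 17 for STAT5B, 6 for HDAC3, 2 for the no-target hairpin, 6 for STAT5A against STAT5B and 198 for LSD1 against HDAC3. Without the 5 libraries they were 874, 2, 11, 5 and 8 for IL3, STAT5A, STAT5B, LSD1 and HDAC3, and 19 for LSD1 against HDAC3, where HDAC3 is left with 1 library that is assumed to vary like the others.

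Leaving out each library in turn gave 302 (without stimulated replicate 4) to 597 genes for IL3 and 2 to 13 for STAT5A (2 without no-target replicate 1 or 5, 3 without 3 or 4, 13 without 2). It gave 7 to 213 for STAT5B (7, 13 and 213 without its replicates 3, 2 and 1, and 8, 9, 10 and 23 without no-target replicates 4, 1, 3 and 5), with 40 of the 41 genes among the 213. It gave 5 to 60 for LSD1 (5 and 60 without its replicates 2 and 3, and 8, 9 and 7 without no-target replicates 1, 4 and 5) and 0 to 9 for HDAC3 (9 without its replicate 1, 0 without replicate 2 or 3 or no-target replicate 2, 1 without no-target replicate 1, 3 or 5). STAT5A against STAT5B ranged from 2 to 9 (9 without STAT5A replicate 3, 6 without STAT5B replicate 1), LSD1 against HDAC3 from 7 to 409 (7 and 409 without LSD1 replicates 2 and 1, and 21, 56 and 25 without HDAC3 replicates 1, 2 and 3), and the no-target hairpin stayed at 0.

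With an estimated correlation, 2 lists passed for IL3 and 0, 0, 0, 0, 0, 0 and 0 in the other comparisons, where camera with a preset correlation passed 6 for IL3, 7, 4, 11 and 6 for the knockdowns of STAT5A, STAT5B, LSD1 and HDAC3, 3, 1 and 10. With fry, 3 passed for IL3, 1 for STAT5A, 4 for STAT5B, 0 for LSD1, 0 for HDAC3, 0 for the no-target hairpin, 0 for STAT5A against STAT5B and 3 for LSD1 against HDAC3. The IL3-induced medians of -0.19 (STAT5A), -0.19 (STAT5B) and -0.29 (LSD1) and the repressed medians of 0.18, 0.21 and 0.29 lost their call with an estimated correlation (adjusted p = 0.251 to 0.471) and with fry (adjusted p = 0.185 to 0.239), which compares the set with no other genes. Without a filter the repressed median for LSD1 was 0.28 (adjusted p = 0.0501; 9.47e-09 to 0.251 over all alternatives). For HDAC3 the induced median was 0.0939 with no minimum fold for the set (adjusted p = 0.00816) and 0.11 with a replicate block (adjusted p = 0.0239), both past the threshold, and -0.18 without the 5 libraries (adjusted p = 0.0490), the reverse sign on 1 HDAC3 knockdown library, with adjusted p from 0.00816 to 0.896 over all its alternatives. The repressed median for HDAC3 was -0.0266 with no minimum fold (adjusted p = 0.491; 0.0866 to 0.998 over all alternatives).

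By library left out, induced medians ranged from -0.0665 (without HDAC3 replicate 1) to 0.12 for HDAC3, past the threshold without HDAC3 replicate 2 (0.11) or 3 (0.12) or no-target replicate 4 (0.12). Repressed medians ranged from -0.20 (without HDAC3 replicate 3; -0.06 without replicate 2) to 0.14 for HDAC3, and from 0.12 to 0.28 for STAT5B, where the call ended without no-target replicate 1 (0.12) or STAT5B replicate 2 (0.17) or 1 (0.24). The induced score for HDAC3 ranged from -0.0768 (without its replicate 1; -0.01 without no-target replicate 3) to 0.15, and the repressed score from -0.16 to 0.0858 (without its replicate 1). The exact permutation test of the induced score passed for STAT5A (-0.27), STAT5B (-0.27) and LSD1 (-0.33) without no-target replicate 3, and that of the repressed score for LSD1 (0.42) without its replicate 2, each at p under 0.05 and in no other omission.

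Genes near 0 changed sign without passing. For Cish with HDAC3 lowered, the log2 fold change was 0.00999 with RLE, 0.00998 with DESeq2, 0.00867 with 2 groups, 0.0917 with a block, 0.19 with a term for class and 0.13 without the 5 libraries, and ranged from -0.24 to 0.12 by library left out. For Pim1 it was -0.11 with a term for class and -0.36 without the 5 libraries, and ranged from -0.0532 (without HDAC3 replicate 1; -0.0121 without 2) to 0.36. For Myc it ranged from -0.00512 (without HDAC3 replicate 1) to 0.44, and for Stat5a with STAT5B lowered from -0.0764 (without STAT5B replicate 2; -0.0413 without no-target replicate 4) to 0.19. Genes that passed in an alternative alone included Socs3 with STAT5A lowered by DESeq2 (-2.48, adjusted p = 0.00732; to 0.944 over all), Pim1 with STAT5B lowered by DESeq2 (-1.20, adjusted p = 0.0118) and with a block (-1.24, adjusted p = 0.0492; to 0.492 over all), and Il2ra without LSD1 replicate 3 (4.82, adjusted p = 0.00738; to 1 over all). With the controls divided, correlations of effects were 0.41 for STAT5A with STAT5B, 0.11 and 0.0948 for LSD1 with each and -0.26 for LSD1 with HDAC3; with a term for class they were 0.56 for STAT5A with STAT5B, and -0.0339 and -0.0488 for HDAC3 with each.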

Other observations

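No explanation was tested in this part, and the lists and values below were chosen for mention only after the result was seen. Beyond the lists described above, growth arrest and cytokine withdrawal genes (24 measured), JAK-STAT components (36), the BCL2 family (14), B-lineage markers (8), T or NK cell markers (7), histone transcripts (16) and nuclear-retained RNAs (12) passed camera in none of the 8 comparisons. B-lineage markers had medians from -0.29 with STAT5B lowered to 0.21 with LSD1 lowered, with 0 of 8 called over all genes and 0 adjusted over the list alone in each knockdown. Growth arrest and cytokine withdrawal genes had a median of -0.18 after IL3 (1 higher, Cited2, and 2 lower, Tsc22d3 and Bbc3; 1 higher and 4 lower adjusted over the list alone; adjusted p = 0.0596). Cited2, a co-activator of transcription, rose from 272 ± 54.8 to 803 ± 54.9 CPM (SD, n = 5 each), and the glucocorticoid-response gene Tsc22d3 fell from 22.4 ± 1.84 to 7.98 ± 2.48. Among nuclear-retained RNAs, Snhg5 fell from 74.7 ± 21.7 to 42.4 ± 5.48 CPM (log2 fold change -0.82, adjusted p = 0.00981; 0 higher and 2 lower adjusted over the list alone).

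The levels of the targeted genes in wild type served as background. Stat5a stood at 108 ± 13 CPM in deprived and 91.2 ± 10.6 in stimulated wild type (SD, n = 5 each; adjusted p = 0.488), against 72.3 ± 14.8 with the no-target hairpin. T or NK cell markers had a median of 0.38 with HDAC3 lowered (7 measured; 0 called, 2 higher adjusted over the list alone; adjusted p = 0.0711).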
